A study of Homo sapiens with 5 samples.

How the data were processed

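RNA of MDA-MB-231 cells, an established human line of triple-negative breast cancer, was reverse transcribed with oligo-dT primers and sequenced on an Illumina GAII instrument, per the labels' protocols. There were 5 libraries, 1 per group. A control siRNA (siNT), an siRNA against SET (siSET) and an siRNA against CIP2A (siCIP2A) were applied for 48 hours. The treatment label of siCIP2A names no time, unlike those of siNT and siSET. A PBS control and OP449 at 1 µM were applied for 12 hours. Groups were taken from the sample labels, and each column of the table was matched to a library by its name. The submitters' processing notes name the build hg19, CASAVA and Bowtie 1.0.0, without saying which step each served. The counting program, its use of strand and the normalization method are not given in the sources used here.

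The deposited values are a signal per RefSeq transcript, called scaled counts here, that the authors had already put on a common scale. In each library 100% of the values were whole multiples of the smallest value above 0, within a tolerance of 0.001 reads, so whole reads could be recovered. A read was worth 1.19 scaled counts in siNT, 1.71 in siSET, 1.10 in siCIP2A, 1.13 in PBS and 1.29 in OP449. The table used here held 16383 transcript rows from chromosomes 1 and 10 to 19, from chromosome 2 up to 166.3 Mb, and from alternate contigs of these (42 rows). Genes elsewhere were not analysed here, which includes SET, CIP2A and MYC. Of the rows, 15739 had an accession that matched a current gene symbol. The symbols of 15 rows had been turned into dates and were restored through their accessions. Transcripts of a gene share reads, so each gene was represented by its transcript with the highest mean over the libraries, which gave 10593 genes. Accessions placed at more than 1 position numbered 146, and their reads may be divided or repeated between copies.

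Over the gene table the recovered reads came to 5249363 in siNT, 3640690 in siSET, 5601289 in siCIP2A, 5512565 in PBS and 4761813 in OP449. A count of 0 allows up to 3 reads, which is 3.56 scaled counts in siNT, 5.13 in siSET, 3.31 in siCIP2A, 3.40 in PBS and 3.86 in OP449.

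With 1 library per group, no test between conditions exists and no difference has a replicate check. Log2 folds were taken on log2(value + 1), which understates the folds of low genes. A gene was counted as higher or lower at a fold of at least 2, among genes whose mean over the 2 libraries compared was at least 50 scaled counts. Each ratio without the pseudocount was given a 95% exact Clopper-Pearson interval from the recovered reads of the 2 libraries. Reads carry no molecular identifiers, so these intervals and the floors above cover counting error only, and they compare libraries, not conditions. The comparisons were siSET against siNT, siCIP2A against siNT, OP449 against PBS, and the control siNT against the control PBS. The last differs in time as well as in treatment.

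The 31 gene lists were fixed before the data were examined. For each list with at least 3 members past the floor, the median log2 fold was placed as a percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. A list was described in detail where its percentile was below 1 or above 99. The lists of MYC-induced genes, MYC-repressed genes, PP2A subunits and regulators, and interferon-stimulated genes were always described. Named genes were the 10 with the largest and the 10 with the smallest log2 fold per comparison, and up to 4 members per described list with the largest folds in either direction. Some genes that this rule selects are not reported here. Log2 folds of 2 comparisons were correlated across genes with a mean of at least 50 over all libraries of both comparisons. Genes at least 2-fold in both were counted under the same floor, so a gene high in only 1 library can enter. The values were set beside 200 simulations of unchanged libraries with Poisson counting error. Genes are not independent replicates.

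Alternatives chosen before the data were examined were floors of 20 and 200, no floor, a pseudocount of 10, a fold threshold of 1.5, the added demand that the counting interval exclude equality, and rescaling to equal totals, by the median of ratios or to equal upper quartiles. Means of list members, unmatched random lists and Spearman's rho were planned as well. Alternatives added after seeing the data were PBS as control of the siRNA libraries, every transcript row counted, control libraries not shared between folds, removal of the trend with transcript length and GC content, and an exact binomial test of the recovered reads with Benjamini-Hochberg adjustment at 0.05. Transcript length, GC content and 3′ UTR sequences came from GENCODE transcripts, used for sequence only, since that annotation is on another build than the table. Coordinates are those of the table on hg19, given as whole transcripts counted from 1.

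The 3′ UTR scan covered 5967 genes with a 3′ UTR of at least 50 bases. It scored the mean fold of genes with each of 15684 heptamers present in at least 50 genes, given 3′ UTR length, GC content and expression, in units of its standard error, with log2 folds limited to 1.5 in size. Scores were set beside 100 shuffles of the folds over genes.

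The computations were tested on simulated data with the real genes and depths and with Poisson counting error only. The simulated libraries hold no variation between cultures or preparations, so the results below give no false-call rate for real libraries. For siSET against siNT, 100% of genes changed 3-fold were counted, 0% of those changed 1.5-fold, and 0 of 5884 unchanged genes. For siCIP2A against siNT these were 100%, 1.01% and 0 of 5901. For OP449 against PBS they were 99%, 2% and 0 of 5896, and for siNT against PBS 99%, 1% and 0 of 5891. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.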

Results

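The series measured gene expression in MDA-MB-231 cells after silencing SET or CIP2A, endogenous inhibitors of the tumour suppressor phosphatase PP2A, and after treatment with OP449, described in the series as a SET antagonist. Its title sets these against the transcription factor MYC. There were 5 libraries, 1 per group, with 3640690 to 5601289 recovered reads over 10593 genes. The siSET library was the shallowest and siCIP2A the deepest. The transcripts of SET, CIP2A and MYC lie outside the part of the genome covered by the table used here, so the extent of silencing and the level of MYC were not analysed here, and the siRNA labels could not be checked against their targets. No difference below has a replicate check. Intervals in brackets are 95% exact counting intervals of the log2 ratio of 2 libraries. They do not cover variation between cultures.

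The first comparison asked which genes differ when SET is silenced. Genes of inflammatory signalling were lower in siSET than in siNT. CSF3, the cytokine G-CSF, stood at 49.6 scaled counts against 319, a log2 fold of -2.66 [-3.29 to -2.13], from 29 and 269 reads. IL24 was 4.87-fold lower, with a log2 fold of -2.28 [-2.56 to -2.02]. IL1A, the cytokine interleukin-1 alpha, was 4.31-fold lower, at -2.10 [-2.50 to -1.74]. MYOF, a membrane repair protein of the ferlin family, was 3.43-fold lower at far greater depth, from 1327 reads against 6564, at -1.78 [-1.86 to -1.69]. The gene of ID3, an inhibitor of basic helix-loop-helix transcription factors, was the highest, at 339 scaled counts against 93.6 and a log2 fold of 1.84 [1.47 to 2.25]. Against PBS, siSET stood at -0.47 for CSF3, -0.49 for IL1A and 0.47 for ID3, each under 2-fold, and at -1.45 for IL24 and -1.67 for MYOF.

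Of 6085 genes past the floor, 24 were at least 2-fold higher in siSET and 48 at least 2-fold lower. Other genes among the lowest were TMEM45B (-2.29), EDN2, which encodes endothelin 2 (-1.76), PRSS22 (-1.64), the BMP antagonist NOG (-1.58) and GDPD5 (-1.57). The other highest were GALNT13 (1.76), MATN3 (1.69), SLC38A4 (1.68), ATOH8 (1.56), ACCN2, now named ASIC1 (1.54), RPS27L (1.45), RNF141 (1.38), MPP2 (1.31) and ZNF268 (1.29). On hg19 the transcript of CSF3 spans chromosome 17 from 38171688 to 38174065, that of IL1A chromosome 2 from 113531493 to 113542971, that of IL24 chromosome 1 from 207070789 to 207077484, that of MYOF chromosome 10 from 95066187 to 95242074 and that of ID3 chromosome 1 from 23884410 to 23886322. With PBS as the control, 17 genes were at least 2-fold higher and 23 lower. Of the 48 lower genes, 13 were also at least 2-fold lower than PBS, and siNT stood above PBS for 45. Of the 24 higher genes, 5 were also at least 2-fold higher than PBS, and siNT stood below PBS for 22. Both sets were picked by their ratio to siNT, which alone favours genes where siNT departs from PBS. The counts therefore cannot tell whether siNT is unusual. EDN2 stood at -0.15 against PBS. ATOH8 was lower than PBS in siSET, at -0.68. PRSS22 stood at 0.71 there, from 37.6 scaled counts in siSET and 22.7 in PBS. That pair was below the floor, so the direction of PRSS22 against PBS is uncertain.

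The 12 measured genes of the NF-kB and inflammatory list were all below siNT in siSET, 11 of them with an interval below 0. Their median log2 fold was -0.56, at percentile 0 of matched random lists, the mean was -0.85, and the median against PBS was -0.37. Besides CSF3 and IL1A, the largest differences were IL1B, at -1.09, and BIRC3, an inhibitor of apoptosis proteins, at -0.97. In siNT this list was itself above PBS, with a median of 0.19 at percentile 99.6. Of 21 ATF4 and amino acid response genes, 18 were lower, with a median of -0.25 at percentile 0. These included the glutathione-degrading enzyme CHAC1 at -0.93, CTH at -0.77, ATF3 at -0.64 and the tRNA synthetase YARS at -0.59. Against PBS the ATF4 list had a median of -0.34 at percentile 0, with 17 of 20 lower. Immediate early and AP-1 genes had a median of -0.20 at percentile 0.53, with 10 of 13 lower, among them ATF3, which is on both lists, KLF2 at -0.50 [-1.11 to 0.07], CYR61 at -0.40 and FOSL1 at -0.37. Against PBS this list's median was -0.04 at percentile 22.5. ERK pathway output genes had a median of -0.19 at percentile 0.65, with 8 of 12 lower. EPHA2 stood at -0.45, FOSL1 at -0.37 and ETV4 at -0.32, whereas SPRY2, a feedback inhibitor of the pathway, stood at 0.52. The mean of this list was -0.11. Against PBS the list was at percentile 38.2, with 6 of 12 lower.

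The 14 measured cholesterol and sterol synthesis genes were above siNT in siSET, with a median of 0.39 at percentile 100. The fatty acid desaturase gene SCD stood at 0.62, IDI1 at 0.57 and DHCR7 at 0.53. In siNT the same list was below PBS, with a median of -0.35 at percentile 0, and siSET against PBS gave a median of 0.02 at percentile 55.2. NRF2 and oxidative stress genes had a median of 0.20 at percentile 99.8 and a mean of 0.12, with 8 of 12 higher. The ferritin light chain gene FTL stood at 0.44, EPHX1 at 0.33, PRDX1 at 0.32 and OSGIN1 at -0.39. Lysosome and autophagy genes had a median of 0.16 at percentile 99.3, with 14 of 17 higher. GABARAPL1 stood at 0.75, LAMP1 at 0.46, NPC2 at 0.33 and ULK1 at -0.50. Nuclear oxidative phosphorylation genes had a median of 0.10 at percentile 99.1, with 29 of 41 higher, among them NDUFA7 at 0.78, NDUFB10 at 0.58, SDHC at 0.48 and ATP5G2 at 0.46. Against PBS the lysosome list was at percentile 95.2 and the oxidative phosphorylation list at 97.9.

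MYC-induced genes were not lower as a group in siSET. Of 37 measured, 20 were above siNT and 17 below, and the median was 0.05 at percentile 85.5. Against PBS the median was 0.01. TMEM97 stood at 1.12 [0.93 to 1.32], the methyltransferase gene PRMT3 at 0.50, RRP12 at -0.41 and SORD at 0.38. The 9 MYC-repressed genes had a median of 0.07 at percentile 78.2 and a mean of 0.14, with TXNIP at 0.73, CDKN1B at 0.28, GADD45B at -0.26 [-0.59 to 0.06] and BTG1 at 0.24. The 17 genes of PP2A subunits, regulators and inhibitors had a median of 0.04 at percentile 71.8. PPP2R2D stood at -0.72, the PP2A methyltransferase gene LCMT1 at 0.53, STRN at 0.51 and PPP2R1B at 0.46. The 23 interferon-stimulated genes had a median of 0.09 at percentile 87.2 and a mean of -0.0089, with RSAD2 at -1.44, IFI6 at 0.65, ISG15 at -0.51 and OAS2 at 0.44. Against PBS the interferon list had a median of 0.19 at percentile 99.8.

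**Figure D1:**
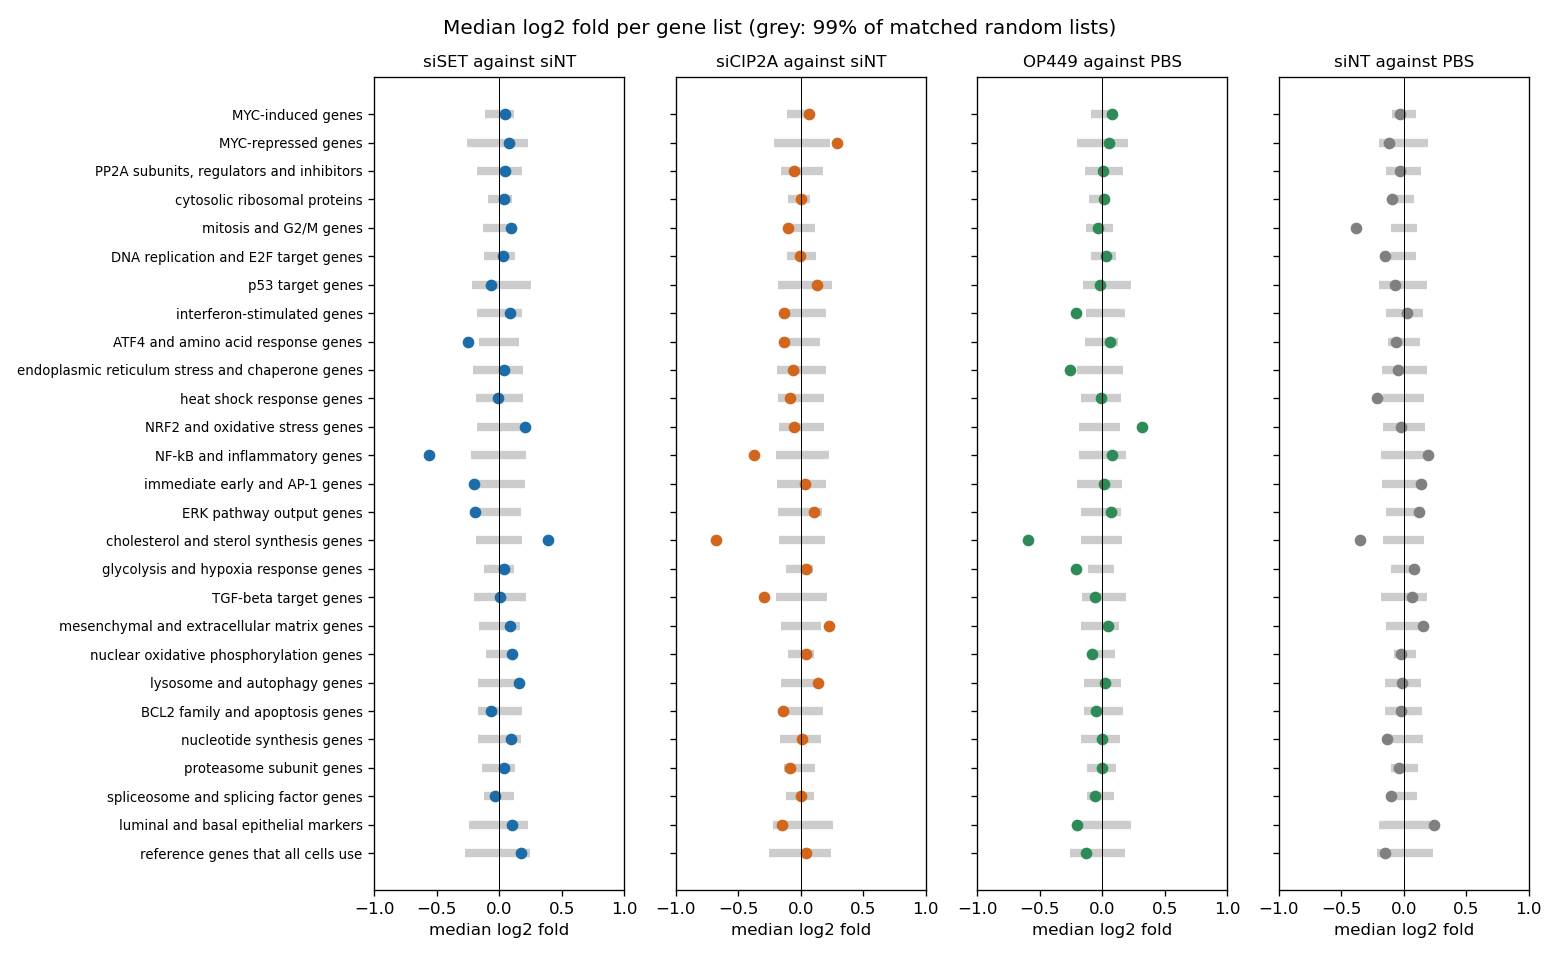
Median log2 fold (x axis) of each gene list with at least 3 members past the floor (y axis), in 1 panel per comparison. Points are medians over genes of 1 library against 1 library and grey bars hold 99% of matched random lists. Sterol synthesis genes sit at 0.39 in siSET, -0.68 in siCIP2A and -0.59 in OP449. MYC-induced genes lie between 0.05 and 0.08 in these panels and at -0.03 in siNT against PBS.

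The second comparison asked the same of CIP2A. Cholesterol and sterol synthesis genes were lower in siCIP2A than in siNT, with a median log2 fold of -0.68. In that list, SCD stood at 2607 scaled counts against 8853, a log2 fold of -1.76 [-1.83 to -1.70], from 2361 and 7470 reads. The endothelial lipase gene LIPG was 3.64-fold lower, at -1.84 [-2.35 to -1.39]. The lowest gene was RASD1, a Ras-related GTPase induced by glucocorticoids, at 12.2 scaled counts against 102 and a log2 fold of -2.97 [-4.12 to -2.16] from 11 and 86 reads. The metallothionein gene MT1X was the highest, 3.26-fold above siNT at 1.70 [1.45 to 1.97]. Metallothionein genes are close relatives, and the way their shared reads were counted is not given in the sources used here.

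Of 6103 genes past the floor, 29 were at least 2-fold higher in siCIP2A and 39 lower. Other genes among the lowest were C17orf28, now named HID1 (-2.01), the cytokine gene IL11 (-1.82), the tetraspanin gene CD82 (-1.60), the adhesion molecule gene VCAM1 (-1.60), LAPTM5 (-1.52) and PRSS22 (-1.49). The other highest were the phosphatase gene PTPRR (1.68), CD22 (1.52), PITPNM3 (1.46), RAP1GAP2 (1.38), MEGF6 (1.32), the kinase gene DYRK2 (1.29), the integrin gene ITGB3 (1.29), ZNF268 (1.28) and GOLGA7B (1.27). On hg19 the transcript of SCD spans chromosome 10 from 102106772 to 102124587, that of LIPG chromosome 18 from 47088427 to 47119276, that of RASD1 chromosome 17 from 17397755 to 17399707 and that of MT1X chromosome 16 from 56716382 to 56718107. Against PBS, 19 of the 39 lower genes and 11 of the 29 higher genes also differed at least 2-fold in the same direction. siNT stood above PBS for 28 of the lower genes and below PBS for 25 of the higher genes. These sets too were picked by their ratio to siNT. PRSS22 in siCIP2A stood at 0.86 against PBS, but that pair was below the floor, so its direction there is uncertain.

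Of the 14 measured sterol synthesis genes, 13 were lower in siCIP2A, 10 with an interval below 0, and the median was -0.68 at percentile 0. DHCR7, which makes cholesterol from its last precursor, stood at -0.88. Against PBS, where siNT was also lower, the median was -0.88. NF-kB and inflammatory genes had a median of -0.38 at percentile 0, with 10 of 13 lower. IL11 stood at -1.82, CSF3 at -1.36 and BIRC3 at -1.31, and the collagenase gene MMP1 at 0.79. Against PBS the list's median was -0.07 at percentile 15.8. IL1A stood at 0.10 against siNT in siCIP2A. TGF-beta target genes had a median of -0.29 at percentile 0.01, with 12 of 14 lower. Besides IL11, THBS1 stood at -0.99, TGFB2 at -0.91 and ANGPTL4 at 1.11. Without a floor the median was -0.11, and against PBS it was -0.16 at percentile 1.14, with 10 of 15 lower. ATF4 and amino acid response genes had a median of -0.13 at percentile 0.98 and a mean of -0.20, with 15 of 21 lower. Among them were CHAC1 with an interval of [-1.66 to -0.39], the amino acid transporter genes SLC7A1 at -0.94 and SLC7A5 at -0.61, and CTH at -0.82. Against PBS the ATF4 list had a median of -0.17 at percentile 0.30, with 19 of 20 lower.

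Mesenchymal and extracellular matrix genes had a median of 0.23 at percentile 99.95 in siCIP2A, with 11 of 17 higher. ZEB2 stood at 0.83 and LAMC1 at 0.64, whereas COL1A1 stood at -0.91 and PLAU at -0.59. The mean of the members was 0.07, and the median without a floor was 0.12. In siNT this list was above PBS, with a median of 0.15 at percentile 99.7. MYC-repressed genes had a median of 0.29 at percentile 99.9, with 7 of 10 higher. TXNIP stood at 0.80, CDKN1C at 0.62, BTG2 at 0.61 [-0.02 to 1.28] and THBS1 at -0.99. The mean was 0.19, and the median against PBS was 0.16 at percentile 96.1. MYC-induced genes had a median of 0.06 at percentile 93.6, with 23 of 37 higher. ODC1, the ornithine decarboxylase gene, stood at -1.13 [-1.23 to -1.02], PRMT3 at 0.66, CDK4 at 0.53 and SORD at 0.47. Against PBS the MYC-induced median was -0.01 at percentile 39.3, with 18 above and 19 below. Interferon-stimulated genes had a median of -0.13 at percentile 0.90, with 14 of 23 lower, among them IFI44 at -1.24, RSAD2 at -1.21, OASL at -0.97 and IFIT1 at -0.82. With a floor of 200 that median was 0.04 and without a floor -0.29, the mean was -0.26, and against PBS the list was at percentile 1.81. PP2A genes had a median of -0.06 at percentile 17.6 and a mean of -0.02, with STRN3 at -0.63, LCMT1 at 0.37, PPP2R1B at 0.33 and PPP2R5A at 0.32.

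**Figure D2:**
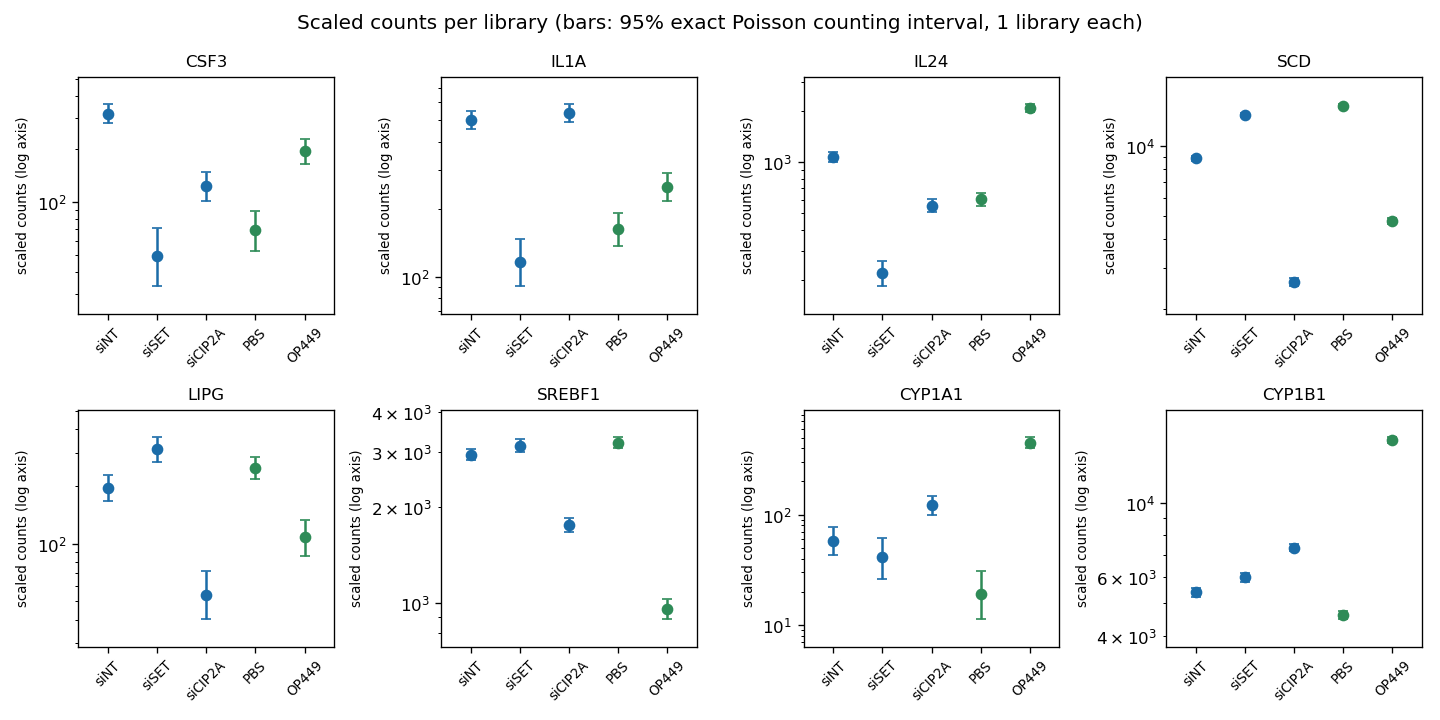
Scaled counts (y axes, log scale) of 8 genes in each of the 5 libraries (x axes). Bars are 95% exact Poisson counting intervals of 1 library and are often smaller than the points. CSF3 reaches 319 in siNT and 69.1 in PBS, SCD is lowest in siCIP2A at 2607, and CYP1A1 is highest in OP449 at 451.

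The third comparison asked which genes differ after 12 hours of OP449. The highest gene was CYP1A1, a xenobiotic-metabolizing cytochrome. It stood at 451 scaled counts against 19.3, a log2 fold of 4.48 [3.85 to 5.34], from 350 and 17 reads. Its relative CYP1B1 stood at 15460 against 4617, at 1.74 [1.69 to 1.80], from 12000 and 4073 reads. ANGPTL4, a secreted inhibitor of lipoprotein lipase, was 9.09-fold higher, at 3.12 [2.43 to 4.03]. SREBF1, which encodes a transcription factor of lipid synthesis, was the lowest, at 953 against 3201 and -1.75 [-1.87 to -1.63]. SCD stood at 4782 against 14804, at -1.63 [-1.68 to -1.58].

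Of 6097 genes past the floor, 18 were at least 2-fold higher in OP449 and 18 lower. The other highest were CRIP2 (2.36), IL24 (1.79), SHISA2 (1.76), CSF3 (1.49), SCG5 (1.44), IL28RA, now named IFNLR1 (1.28), and BMF, a BH3-only promoter of apoptosis (1.21). Others among the lowest were PRICKLE1 (-1.37), the circadian output gene DBP (-1.35), PPL (-1.34), LIPG (-1.20), C10orf54, now named VSIR (-1.19), VCAM1 (-1.19) and the circadian gene PER3 (-1.13). On hg19 the transcript of CYP1A1 spans chromosome 15 from 75011884 to 75017877, that of CYP1B1 chromosome 2 from 38294746 to 38303323, that of ANGPTL4 chromosome 19 from 8429011 to 8439257 and that of SREBF1 chromosome 17 from 17714665 to 17740325.

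Of 14 sterol synthesis genes, 12 were lower in OP449, 11 with an interval below 0. Their median was -0.59 at percentile 0. Glycolysis and hypoxia response genes had a median of -0.21 at percentile 0 and a mean of -0.13, with 24 of 29 lower. ALDOC stood at -0.86, INSIG2 at -0.73 and the carbonic anhydrase gene CA12 at -0.61, while ANGPTL4, also on this list, was higher. All 10 measured endoplasmic reticulum stress and chaperone genes were lower, with a median of -0.26 at percentile 0.03. HERPUD1 stood at -0.42, CALR at -0.34, PDIA6 at -0.32 and HYOU1 at -0.31. Nuclear oxidative phosphorylation genes had a median of -0.08 at percentile 0.32, with 34 of 41 lower, among them NDUFS3 at -0.32, NDUFA13 at -0.30, UQCRFS1 at -0.28 and NDUFB7 at -0.24. Interferon-stimulated genes had a median of -0.21 at percentile 0, with 19 of 23 lower. IFI6 stood at -0.78, IFI35 at -0.43, EIF2AK2 at 0.45 and RSAD2 at 0.62 [-0.02 to 1.29]. NRF2 and oxidative stress genes had a median of 0.32 at percentile 100, with 8 of 12 higher. GCLM, a subunit of the enzyme that limits glutathione synthesis, stood at 1.03, the ferritin heavy chain gene FTH1 at 0.47, OSGIN1 at 0.45 and AKR1C3 at 0.43.

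MYC-induced genes had a median of 0.08 at percentile 97.8 in OP449, with 24 of 37 above PBS. RRP12 stood at 0.77, HK2 at -0.55, ODC1 at 0.55 and PRMT3 at 0.35. With the trend in transcript length and GC content removed, the percentile was 99.9. The 10 MYC-repressed genes had a median of 0.06 at percentile 77.3 and of -0.04 with a floor of 200, with TXNIP at 0.72, GADD45B at -0.51, FTH1 at 0.47 and THBS1 at 0.47. PP2A genes had a median of 0.00 at percentile 38.6 and a mean of 0.02, with STRN at 0.51, PPP2R5E at 0.35, the PP2A methylesterase gene PPME1 at -0.33 and PPP2R3C at -0.23 [-0.47 to 0.00].

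**Figure D3:**
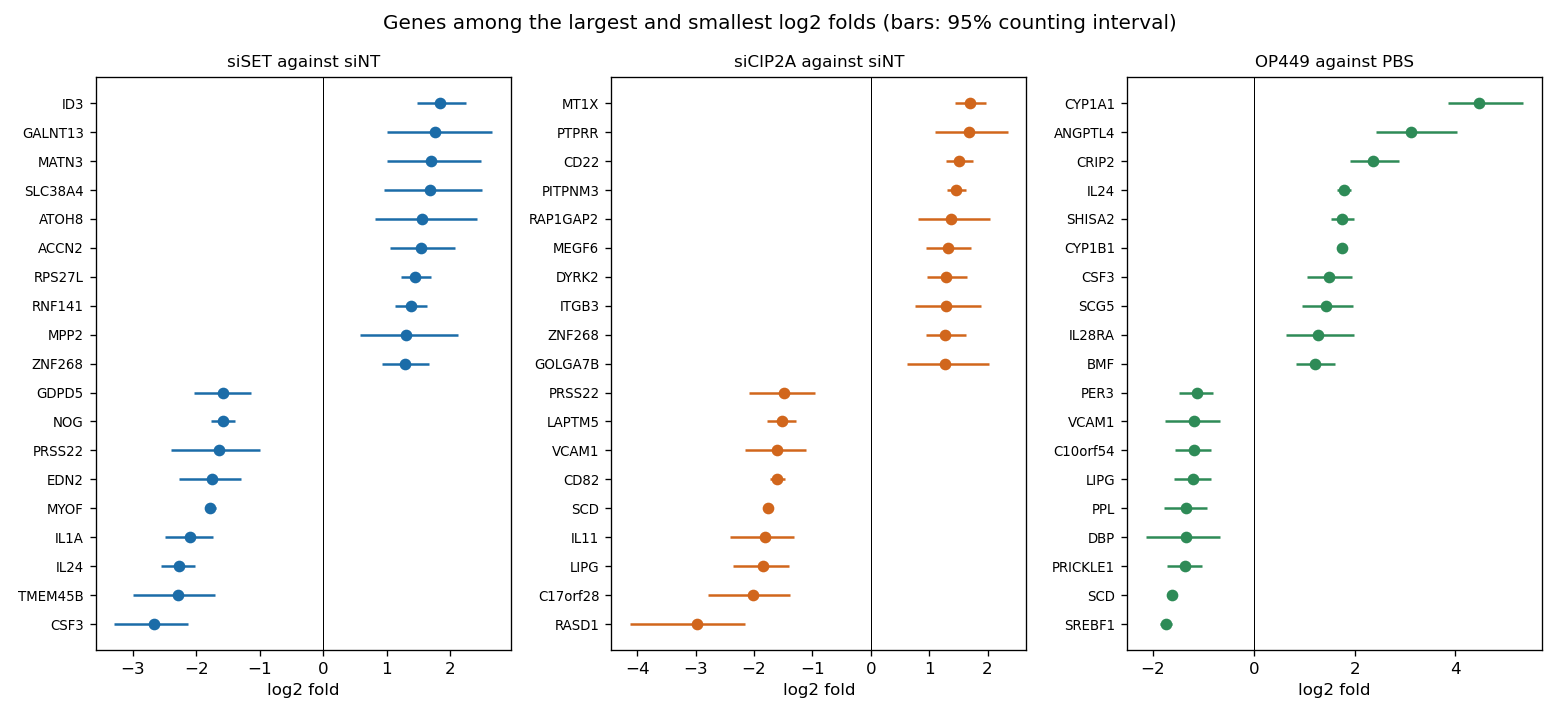
Log2 folds (x axes) of genes among the 10 highest and 10 lowest (y axes) of each comparison of 1 library with 1 library, with 95% counting intervals as bars. CSF3 is lowest in siSET at -2.66, RASD1 in siCIP2A at -2.97 and SREBF1 in OP449 at -1.75, and CYP1A1 in OP449 is the highest at 4.48.

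The 2 controls were compared as the background for these differences. Of 6077 genes, 15 were at least 2-fold higher in siNT than in PBS and 9 lower. CSF3 stood at 2.19 and IL1A at 1.61 in siNT, and ID3 at -1.37. All 27 measured mitosis and G2/M genes were lower in siNT, with a median of -0.38 at percentile 0. Further lists below the 1st percentile were DNA replication and E2F targets (-0.15), heat shock genes (-0.21), ribosomal proteins (-0.09), nucleotide synthesis genes (-0.13) and splicing factors (-0.10). Luminal and basal epithelial markers were at 0.24, percentile 99.8. Of the 27 lists that could be placed, 10 lay below percentile 1 or above 99 between these controls, against 8 for siSET, 7 for siCIP2A and 6 for OP449.

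The remaining lists lay between those percentiles in the 3 treated comparisons. Medians in siSET, siCIP2A and OP449 in turn were 0.04, 0.00 and 0.01 for ribosomal proteins, 0.09, -0.10 and -0.03 for mitosis genes, and 0.03, -0.01 and 0.03 for DNA replication genes. They were -0.06, 0.13 and -0.02 for p53 targets, -0.01, -0.09 and -0.01 for heat shock genes, and -0.07, -0.14 and -0.05 for apoptosis genes. Nucleotide synthesis genes were at 0.10, 0.01 and -0.01, proteasome subunits at 0.04, -0.09 and 0.00, and splicing factors at -0.03, 0.01 and -0.06. Epithelial markers were at 0.10, -0.15 and -0.20, and reference genes at 0.18, 0.04 and -0.13. Blood and immune markers were represented by CD68 alone, at -0.01, 0.11 and 0.15, and stromal markers by COL1A1 alone, at -0.63, -0.91 and 0.20. Of the 57 replication-dependent histone genes listed, only 6 were among the genes analysed here, and none of these passed the floor. Mitochondrially encoded genes were not analysed here.

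The 3 treatments were then set side by side across genes. Folds of siSET and siCIP2A had a Pearson r of 0.39 over 6096 genes, and 5 genes were at least 2-fold lower in both (CCDC88B, CSF3, LAPTM5, PRSS22 and SCG5), against 0.29 for independent lists and 0 in simulation. For genes at least 2-fold higher in both, 7 were found (GALNT13, ITGB3, MTMR6, RHOBTB1, RPS27L, SLC38A4 and ZNF268), against 0.10 for independent lists and 0.01 in simulation. Those outside the naming rule, CCDC88B, MTMR6, RHOBTB1 and SCG5 in these comparisons, were named after their values were seen. Both folds use siNT, and simulated unchanged libraries gave an r of 0.46. The covariance was 0.0392 against a simulated 0.00887. Less the simulated value, the covariance was 0.0303, against 0.0078 and -0.0017 in the 2 pairings without a shared control described next. With 1 control library the control could not be split, and most or all of the excess may come from it. Neither the independent lists nor the simulation allows for a siNT library that differs by more than counting error. Without a shared control, r was 0.08 for siSET against PBS with siCIP2A against siNT, where LAPTM5 was the 1 gene lower in both and 2 were higher in both (CYP1A1 and LCP1). It was -0.02 for siSET against siNT with siCIP2A against PBS, where LAPTM5 was again the 1 gene lower in both and 2 were higher in both (ITGB3 and RHOBTB1). The floor for these counts is on the mean over all libraries of both comparisons. CYP1A1 passed it, but stood at 41.1 scaled counts in siSET and 19.3 in PBS, below the floor for that pair alone. GALNT13 and SLC38A4, higher in siSET and siCIP2A against siNT, were likewise below the floor for siCIP2A with siNT alone. GALNT13 stood at 60.7 in siCIP2A and 22.5 in siNT, and SLC38A4 at 68.5 and 26.1. LCP1 was named after its value was seen.

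SET silencing and OP449 share no control, and their folds had an r of -0.06 over 6094 genes, with a simulated r of -0.002. Spearman's rho was -0.01, and r without a floor was -0.02. PROM2 was the 1 gene at least 2-fold lower in both and none was higher in both. The 7 genes lower in siSET and higher in OP449 were ANGPTL4, CSF3, FAIM3, IL24, MMP1, SCG5 and SHISA2, against 0.13 for independent lists. ANGPTL4 stood at 18.8 scaled counts in siSET and 47.4 in siNT, below the floor for that pair alone. MMP1 was below that floor too, so neither was counted as lower in siSET against siNT. With PBS as the control of siSET, which OP449 then shares, IL24 stood at -1.45. MMP1 stood at -2.67, but its mean over siSET and PBS was below the floor, so it does not count as 2-fold lower there. The others missed the 2-fold threshold there, with FAIM3 at -0.82, SHISA2 at -0.69, CSF3 at -0.47, SCG5 at -0.26 and ANGPTL4 at 0.05, and so did PROM2, at -0.72. CIP2A silencing and OP449 had an r of 0.15 over 6094 genes, with a simulated value of 0.0002, and an r of 0.05 without a floor. There were 5 genes lower in both, among them C17orf28, LIPG, SCD and VCAM1, against 0.12 for independent lists, and ANGPTL4, CYP1A1 and IL1RN were higher in both. Against PBS, IL1RN in siCIP2A stood at 0.90. CSF3, IL11 and SCG5 were lower in siCIP2A and higher in OP449. Against PBS, CSF3 in siCIP2A stood at 0.83 and SCG5 at 0.25, while IL11 stayed lower, at -2.08. The siRNAs acted for 48 hours, a time that the treatment label of siCIP2A does not name, and OP449 for 12. PROM2, FAIM3 and IL1RN were named after their values were seen.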

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

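The tests with PBS as the siRNA control, with every transcript row, with unshared controls, without the length and GC trend, and of the recovered reads were chosen after the data were seen. No paired analysis was possible because each group holds 1 library. Intervals of list medians and correlations in this section came from resampling genes, with 2000 and 500 draws, and those of named genes are counting intervals. Genes are no replicates, so staying within an interval says nothing of variation between cultures. The 3 rescalings left every count within 1.5 times and every median and correlation within its interval. A pseudocount of 10 moved 1 result, the genes lower in siNT than in PBS, to 4. Counts below are of genes higher and then lower, for siSET, siCIP2A, OP449 and siNT in turn. Where a count is missing it stayed within 1.5 times. A floor of 20 gave 47 higher for siSET, 52 and 59 for siCIP2A, 36 and 35 for OP449, and 28 and 23 for siNT. A floor of 200 gave 10 and 22, 13 and 14, 7 and 7, and 3 and 3. No floor gave 411 and 542, 446 and 434, 374 and 406, and 431 and 381. A threshold of 1.5 gave 173 and 262, 169 and 204, 122 and 108, and 100 and 85. These follow from more or fewer genes being admitted. Every transcript row gave 45 higher for siSET, 50 higher for siCIP2A, 35 and 30 for OP449, and 15 lower for siNT. The exact binomial test of the recovered reads, which compares libraries and not conditions, gave 888 and 938, 1018 and 1038, 846 and 809, and 819 and 785. With PBS as control, 23 genes were lower in siSET, and 4 list medians and 26 named genes left their intervals. Those medians were immediate early genes (-0.04) and sterol genes (0.02) in siSET, and sterol genes (-0.88) and NF-kB genes (-0.07) in siCIP2A. As means of their members, 2 lists left their intervals, NF-kB genes in siCIP2A (-0.45) and glycolysis genes in OP449 (-0.13). Within their intervals but over 1.5 times from the median, means were -0.85 for NF-kB, -0.11 for ERK output, 0.12 for NRF2 and 0.14 for MYC-repressed genes in siSET, -0.20 for ATF4, -0.26 for interferon, 0.19 for MYC-repressed, -0.023 for PP2A and 0.07 for mesenchymal genes in siCIP2A, and 0.022 for PP2A genes in OP449. Without a floor, siCIP2A gave -0.11 for TGF-beta, -0.29 for interferon and 0.12 for mesenchymal genes. Against PBS, ERK output genes (-0.0022), NF-kB genes (-0.37) and interferon genes (0.19) in siSET, and MYC-repressed (0.16) and TGF-beta genes (-0.16) in siCIP2A, also stayed within their intervals. The mean had the opposite sign to the median for interferon genes (-0.0089), epithelial markers (-0.017) and ribosomal proteins (-0.00092) in siSET, for immediate early genes in siCIP2A (-0.076) and OP449 (-0.030), and for TGF-beta (0.12), apoptosis (0.025), nucleotide synthesis (0.045) and proteasome genes (0.0099) in OP449. The 2-fold genes all had intervals that excluded equality. The siSET and siCIP2A correlation was 0.45 without a floor, 0.085 with siSET against PBS, and -0.017 with siCIP2A against PBS, which both remove the shared control library. The siSET and OP449 correlation was -0.021 without a floor and -0.0097 as Spearman's rho, and that of siCIP2A and OP449 was 0.052 without a floor. The cause was not tested. The medians of MYC-induced genes stayed within their intervals under each alternative run, but against PBS that of siSET was 0.010 and that of siCIP2A turned to -0.0071. With the length and GC trend removed they were 0.019 and 0.037. Rescaling to equal upper quartiles gave 0.016 in siSET, and by median of ratios 0.041 in siCIP2A. Equal upper quartiles also gave 0.059 for interferon, 0.043 for MYC-repressed and 0.011 for PP2A genes in siSET, and 0.035 for MYC-repressed genes in OP449. A floor of 200 gave -0.085 for PP2A genes in siCIP2A and turned MYC-repressed genes in OP449 to -0.038. PP2A genes in OP449, at 0.0037, gave 0.030 with equal totals, -0.013 by median of ratios and -0.018 with equal upper quartiles. Interferon-stimulated genes in siCIP2A turned to 0.039 with a floor of 200, and the cause was not tested. Against PBS, PRSS22 turned to 0.71 in siSET and 0.86 in siCIP2A, and ATOH8 to -0.68 in siSET. Both pairs of PRSS22 with PBS were below the floor of 50, so its turned sign is uncertain. Depth limits siSET most, where 3 reads are worth 5.13 scaled counts.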

Other observations

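Outside the lists fixed in advance, 3 groups were put together after their values were seen. Metallothionein genes, which bind zinc and copper, were higher in siCIP2A than in siNT, with MT1X at 1.70, MT1E at 1.00 and MT2A at 0.72. Against PBS their median was 0.42, since siNT was below PBS at -0.59. Target genes of the aryl hydrocarbon receptor, the sensor of planar xenobiotics, were higher in OP449. Besides CYP1A1 and CYP1B1, ALDH1A3 stood at 0.96 and NQO1 at 0.29. CYP1A1 was also above PBS without OP449, at 1.54 in siNT, 1.05 in siSET and 2.59 in siCIP2A. Its siNT and siSET pairs with PBS were below the floor. Circadian clock genes had a median of -0.31 in OP449. DBP stood at -1.35, PER3 at -1.13 and PER1 at -0.69, while ARNTL, whose product drives their transcription, stood at 0.77.

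The tests below that compared with PBS, and those of the heptamer, were chosen after related values had been seen. Those of transcript length and GC content were set out before their results.

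NF-kB and inflammatory genes were lower than siNT in both silenced libraries, and siNT was itself above PBS. In siSET the list was at percentile 0 against PBS too, with a median of -0.37 in place of -0.56. PBS differs in time as well as in treatment, so this cannot exclude the level of siNT as the cause. Mitosis genes, for example, were at percentile 0 against PBS in siNT, siSET and siCIP2A alike. For siCIP2A the level of siNT may account for the group's position, which was at percentile 15.8 against PBS. With the trend in transcript length and GC content removed, the percentile was 0 in siSET and 0.08 in siCIP2A, so that trend is not the whole cause. An effect of silencing SET remains open and has no replicate behind it.

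Sterol synthesis genes lay above siNT in siSET and below control in siCIP2A and OP449. The siSET difference may reflect the low level in siNT, since siSET against PBS was at percentile 55.2. For siCIP2A, a high level in siNT would be needed, and siNT lay below PBS, at percentile 0. Both readings are limited because PBS differs from the siRNA libraries in time as well as in treatment. With the length and GC trend removed, siCIP2A and OP449 both stayed at percentile 0. A lower sterol programme after CIP2A silencing and OP449 is a hypothesis, and cell density and medium were not tested.

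Transcripts with TGCTAGT in the 3′ UTR were lower in siCIP2A, with a score of -8.55 and a mean shift of -0.14 over 399 genes. TGCTAGT was picked as the lowest of 15684 heptamers in siCIP2A against siNT. The lowest of 100 shuffles was -5.27. Of 403 other heptamers with the same bases that share no stretch of 5 bases with it, the lowest scored -3.94, which argues against base composition, and siNT against PBS scored -2.18, below 0, where a high level in siNT would give a score above 0. The score in siCIP2A against PBS was -10.2, but it reuses the siCIP2A library in which the heptamer was picked. OP449 against PBS, with no siRNA, scored -0.88. The siCIP2A library is on neither side of that comparison, so its score cannot tell an effect of the siRNA reagent from a response to CIP2A. With the other siRNA, siSET scored 1.49 against siNT, -0.20 against PBS and 8.89 against siCIP2A. The last of these scores also reuses the siCIP2A library. Seed-like matches of the siCIP2A reagent stay a candidate explanation. CIP2A silencing comes with the same reagent in 1 library, and the siRNA sequences were not used here, so a response to CIP2A itself stays open.

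In siSET against siNT the lowest heptamer was AGAAGAT, at -6.84. It scored -6.08 in siSET against PBS, -0.49 in siCIP2A against siNT and 0.56 in OP449 against PBS. In siNT against PBS the lowest was AGCCTTA, at -6.40, where the lowest of 100 shuffles was -4.83. Against siNT it was the highest heptamer in siSET, at 5.46, and in siCIP2A, at 6.70. The highest of 100 shuffles was 5.56 for siSET and 4.82 for siCIP2A. Against PBS, AGCCTTA scored 0.32 in siSET and 1.19 in siCIP2A, so its shift lay mainly in the siNT library. Its cause, including seed-like matches of the siNT reagent, was not tested. The AU-rich heptamer TATTTAT was the highest in siNT against PBS, at 5.03. TATTTAT scored -6.37 in siSET and -7.17 in siCIP2A against siNT, and -2.72 and -2.67 against PBS.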
